A study of Homo sapiens with 20 samples.

How the data were processed

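Gene expression was measured in PNT1A cells, an established line of non-cancerous human prostate epithelial cells immortalised with SV40. The cells were exposed for 48 h to DMSO (0.4%) or to the compounds BDB and HDB, which the labels name only by these abbreviations, at 1e-08 M (the low dose) or 1e-06 M (the mid dose). The design text of the series writes these doses in a notation that could also be read as 10 times higher, so which is right is not settled, and the doses here are those in the sample labels. A DMSO percentage is recorded for the control samples alone, so whether the treated samples held the same amount is not known. Each of the 5 groups holds 4 samples, and each of the 20 samples was hybridised to 1 array. The labels do not say whether the 4 samples of a group came from separate cultures, so every p-value measures only the spread between samples. The titles of the 4 DMSO samples carry a set tag that no BDB or HDB title carries, and its meaning is not stated. If the controls were handled as a separate set, that could not be told apart from treatment in the comparisons with DMSO.

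Per the labels, RNA was purified on spin columns, checked on a Bioanalyzer, and 25 ng was amplified and labelled with Cy3 for 1-colour hybridisation to an Agilent human array. Per the file headers, the scans were read with Agilent Feature Extraction 11.5.1.1 against the hg19 build. The deposited scanner files hold intensity values: a processed signal, background-subtracted and detrended within each array, and the median signal of each spot and of its local background. The authors also deposited a table of 29681 probes on a log2 scale. How they made it is not stated. When checked against the scanner files, all 20 columns tracked the median spot signal of their own array (Spearman 0.9994 to 0.9999) and shared nearly the same distribution (column medians 7.7 to 7.74), as after quantile normalisation without background subtraction. That table served as an alternative.

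The processed signal of 58717 non-control spots was log2-transformed, and spots marked as non-uniform or as population outliers were left out where a probe had other spots. Replicate spots were averaged into 42405 probes, and the 75th percentile of each array was subtracted. A probe was tested when it lay well above background on all 4 arrays of at least 1 group, with a probe of several spots counted when at least 50% of its spots did. This left 28245 probes. The files pair probes with transcript accessions only, so gene symbols came from a table of human genes (assembly GRCh38.p14, used for names alone): 26364 of the 42405 probes matched a symbol and 16041 did not. The tested probes with a symbol covered 15132 genes, and 25387 of the tested probes lay above background on all 20 arrays.

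One limma model (version 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8) with a mean per group was fitted to all 20 arrays, leaving 15 residual degrees of freedom, with eBayes and an intensity trend. The comparisons were each compound and dose against DMSO, BDB against HDB at each dose, and 1e-06 M against 1e-08 M of each compound, 8 in all, plus an F-test over the 4 contrasts with DMSO. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Each log2 change is given with its standard error from this model, and each interval is a 95% interval.

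Gene lists, 32 in all, were tested with limma's camera at its preset correlation between genes of 0.01, with 1 probe per gene (the brightest) and adjustment over the lists. They cover androgen, estrogen and glucocorticoid response, PPAR targets and fatty acid oxidation, fatty acid synthesis, cholesterol biosynthesis, steroidogenesis, xenobiotic response, NRF2 response, unfolded protein response, heat shock, p53 response, mitosis, DNA replication, replication-dependent histones, apoptosis, NF-kB and inflammatory cytokines, interferon response, hypoxia, glycolysis, oxidative phosphorylation, ribosomal proteins, metallothioneins, extracellular matrix and epithelial-mesenchymal transition (EMT), epithelial junctions, immediate early genes, and TGF-beta and YAP targets. Markers of basal and luminal prostate epithelium, neuroendocrine cells, fibroblasts and smooth muscle, and immune and endothelial cells complete them. Of 617 symbols on the lists, 2 could not be matched. Some lists share genes: the matrix list shares 4 with the TGF-beta and YAP list and 3 with the fibroblast list, and hypoxia shares 3 with glycolysis. The plan tested the lists in the 6 comparisons with DMSO or between compounds, and the same tests of the 2 dose comparisons were added after seeing the data. Camera with an estimated correlation and fry, whose test asks whether a list's genes move one way on balance, were run as alternatives. A list's score in a sample is the mean over its genes of the log2 signal centred on the mean of all samples.

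The named genes follow a rule: in each comparison, genes past the threshold with the largest changes, up to 10 per direction, and where fewer pass, those with the smallest unadjusted p until 6 per direction are named, given as values that did not pass. For each list past its threshold, the 2 members with the largest positive and the 2 with the largest negative change are named, and for other lists only counts are given. A set of 14 genes fixed by name is given in every comparison with DMSO, and the dose comparisons name 3 genes per direction. A few genes that the rule names, 1 of the 14 among them, are left out of the text and figures. The samples, comparisons, tests, lists, naming rule and most of the alternatives were fixed before the data were examined. The rule named 170 genes in 245 gene and comparison pairs. Of these pairs 39 had other tested probes, and in 9 at least 1 other probe had the opposite sign.

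The alternatives were quantile normalisation, another background correction (normexp, offset 50), no probe filter or a stricter one, the authors' table, arrays weighted by quality, slide or replicate number as a block, no intensity trend, a model of only the 2 groups compared, a minimum change of 1.5-fold, the mean over a gene's probes, and leaving out each array in turn. The arrays came from 3 slides (7, 7 and 6 arrays) with all 5 groups on each slide, and the first slide was scanned on a different day from the others. For arrays, their number limits the precision: the median standard error of a log2 change was 0.179. The script was tested on simulated data for BDB at 1e-06 M against DMSO with 28245 probes. It recovered 37.3% of 67 probes changed 1.5-fold, 71.6% of 67 changed 2-fold and 89.4% of 66 changed 3-fold, and called 4 unchanged probes. With the same changes added to the measured values it recovered 32.8%, 70.1% and 95.5%, and called 0 unchanged probes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.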

Results

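The series measured mRNA in 20 samples of PNT1A prostate epithelial cells, 4 in each of 5 groups: DMSO, BDB at 1e-08 M and 1e-06 M, and HDB at 1e-08 M and 1e-06 M. Its title names the screening of potential green plasticizers as the purpose. Between 63.9% and 72.5% of the probes on an array lay well above background, the 75th percentile of the processed signal ran from 575.2 to 891.3, and 0 probes were saturated. Pairs of samples from the same group correlated across probes with a mean r of 0.9881 (30 pairs), and pairs from different groups with a mean of 0.9886 (160 pairs).

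The samples varied most along axes other than treatment. The first principal component held 25.3% of the variance, with 40.5% of it between slides and 17.7% between groups. The second held 18.5%, of which 78.6% lay between slides. In 5 samples the immediate early genes, which growth factors and stress switch on within minutes, scored from 0.51 to 0.67 on the log2 scale, against −0.42 to 0.01 in the other 15. These were DMSO replicate 1, BDB low-dose replicates 2 and 4, and HDB low-dose replicates 3 and 4. Among the members of that list, FOS in these 5 samples lay between −0.23 and 0.15 (log2 relative to the 75th percentile of the array) and between −2.43 and −1.54 in the others, and EGR1 between 3.82 and 4.07 against 1.56 to 2.57. Hypoxia genes scored 0.22 to 0.27 in the 5 samples against −0.18 to 0 in the others, TGF-beta and YAP targets 0.12 to 0.34 against −0.22 to 0.05, and glycolysis 0.1 to 0.18 against −0.13 to 0.02. NRF2 targets scored −0.26 to −0.11 in the 5 samples against −0.11 to 0.15. Scores were also higher without overlap for NF-kB and inflammatory cytokines (0.18 to 0.48 against −0.29 to 0.12) and heat shock (0.09 to 0.21 against −0.17 to 0.04). They were lower without overlap for p53 and DNA damage (−0.29 to −0.17 against −0.06 to 0.15) and the xenobiotic response (−0.52 to −0.1 against −0.04 to 0.24). These lists were picked out after their scores were seen.

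**Figure D1:**
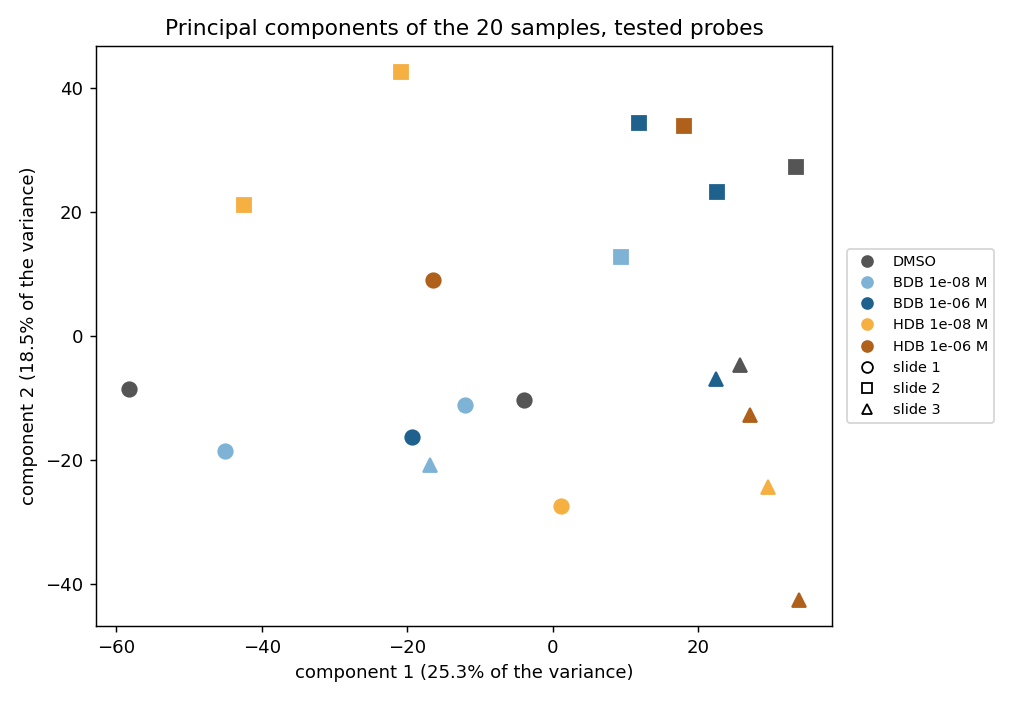
Scores of the 20 samples on the first principal component (horizontal axis, 25.3% of the variance) and the second (vertical axis, 18.5%), from the log2 values of the tested probes. Each point is a sample, its colour the group and its shape the slide. Along the second component, of which 78.6% was between slides, slide 2 lies apart (12.8 to 42.6), while slide 1 (−27.4 to 9) and slide 3 (−42.6 to −4.7) overlap.

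No single gene passed the threshold in any comparison. Across the 5 groups the F-test of limma called 0 of 28245 probes, with 955 at an unadjusted p under 0.05 where about 1412 would arise by chance over independent tests. That count ran from 548 to 1897 with 1 array left out and from 455 (without the 5 samples) to 3826 (array weights) over the other settings, on both sides of 1412. Each of the 8 comparisons also called 0 probes. For 56.4% to 67% of the probes the 95% interval of the change lay within 1.5-fold, and for 88.8% to 92.8% within 2-fold. What follows are therefore calls of gene lists by camera at its preset correlation. With an estimated correlation, and with fry, 0 lists were called in each of the 8 comparisons. Where a list is said to rise or fall, this gives the direction of a camera call, not an established change. Each named gene is given as a value that did not pass. It comes with its standard error and 4 samples per group, or with a bound where a group lay above background on 0 arrays. Changes are on the log2 scale.

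The question of the comparisons with DMSO is which genes each compound moves at each dose. With BDB at 1e-06 M the extracellular matrix and EMT list fell, which holds collagens, matrix proteases and transcription factors of the mesenchymal state. Of its 24 measured members 22 lay below DMSO and 2 above, with a median of −0.21. MMP9, a matrix protease, was −0.88 ± 0.41 and COL1A1, a fibrillar collagen, −0.63 ± 0.27, while SPARC was 0.08 ± 0.15 and ZEB1 0.04 ± 0.1. Markers of basal prostate epithelium fell too, with 13 of 15 below DMSO and a median of −0.15. Among them COL17A1, a component of hemidesmosomes, was −0.92 ± 0.35, with 2 of 4 treated arrays above background, KRT5, the keratin of basal cells, was −0.54 ± 0.57, NOTCH4 was 0.13 ± 0.18 and CD44 0.02 ± 0.1. For these lists the camera adjusted p was 7.4e-08 and 0.00041. Both calls were lost when the correlation between genes was estimated (adjusted p = 0.11 for each with an estimated correlation).

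Cholesterol biosynthesis rose with BDB at 1e-06 M, with 20 of 24 members above DMSO and a median of 0.09 (adjusted p = 0.00026). MVK, mevalonate kinase, was 0.23 ± 0.14, INSIG1 0.22 ± 0.22, SREBF2, the transcription factor of the pathway, −0.11 ± 0.11, and PMVK −0.1 ± 0.1. All 13 replication-dependent histone genes lay above DMSO (median 0.13, adjusted p = 0.0076), led by H2AC8 at 0.32 ± 0.26 and H2AC6 at 0.25 ± 0.28. Neither call held with an estimated correlation (adjusted p = 0.3 for cholesterol and adjusted p = 0.76 for histones).

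A further 6 lists fell with BDB at 1e-06 M by camera. In glycolysis 14 of 17 members lay below DMSO (median −0.1, adjusted p = 0.0034), with GPI at −0.25 ± 0.15 and HK2 at −0.23 ± 0.27, but PFKL at 0.45 ± 0.29 and TPI1 at 0.03 ± 0.1. In the hypoxia response 17 of 20 lay below (median −0.11, adjusted p = 0.013), with CA9 at −0.44 ± 0.21, ANGPTL4 at −0.29 ± 0.24, ADM at 0.12 ± 0.36 and DDIT4 at 0.08 ± 0.14. Of the TGF-beta and YAP targets 13 of 16 lay below (median −0.16, adjusted p = 0.013), with TGFBI at −0.53 ± 0.23, AJUBA at 0.18 ± 0.11 and SMAD6 at 0.06 ± 0.1. Of the immediate early genes 15 of 17 lay below (median −0.17, adjusted p = 0.021), with FOS at −0.68 ± 0.48, JUN at −0.48 ± 0.45, NR4A1 at 0.43 ± 0.59 and FOSB at 0.08 ± 0.18. Of the estrogen response genes 10 of 15 lay below (median −0.05, adjusted p = 0.013), with CA12, a carbonic anhydrase, at −0.62 ± 0.21, PDZK1 at −0.49 ± 0.43, ESR1, the estrogen receptor gene itself, at 0.1 ± 0.17 and AREG at 0.06 ± 0.27. Of 8 fibroblast and smooth muscle markers 7 lay below (median −0.08, adjusted p = 0.013), with COL1A1 lowest, CNN1 at −0.29 ± 0.16 and POSTN at 0.22 ± 0.71. With an estimated correlation the adjusted p was 0.11 for estrogen response, 0.76 for immediate early genes and 0.3 for glycolysis, hypoxia, TGF-beta and YAP targets and fibroblast markers, so these calls were lost. DMSO replicate 1 was among the 5 samples with high immediate early, hypoxia, glycolysis and TGF-beta scores, and without those 5 samples the medians were 0.11 for immediate early genes, −0.03 for hypoxia, −0.08 for glycolysis and −0.07 for TGF-beta and YAP targets, and these 4 calls ended.

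The remaining 22 lists did not pass for BDB at 1e-06 M. Nuclear receptor and xenobiotic lists were among them: androgen response had 5 members above DMSO and 11 below (median −0.1), glucocorticoid response 6 and 7 (0), PPAR targets and fatty acid oxidation 8 and 11 (−0.02), the AHR, CAR and PXR xenobiotic response 6 and 6 (0.06), and steroidogenesis 5 and 9 (−0.03). Fatty acid synthesis had 10 above and 5 below (0.02), oxidative phosphorylation 12 and 11 (0.01) and ribosomal proteins 10 and 15 (−0.03). Among stress lists NRF2 response had 10 above and 10 below (0.01), the unfolded protein response 9 and 11 (−0.01), heat shock 4 and 12 (−0.06), p53 and DNA damage 8 and 12 (−0.01), metallothioneins 3 and 9 (−0.06) and apoptosis regulators 9 and 15 (−0.04). Mitosis had 10 above and 14 below (−0.01) and DNA replication 16 and 9 (0.02). Interferon response had 6 above and 16 below (−0.08, adjusted p = 0.096) and passed with slide as a block (median −0.09, adjusted p = 0.032). NF-kB and inflammatory cytokines had 7 above and 13 below (−0.05) and epithelial junctions 6 and 15 (−0.1). Luminal markers had 2 above and 8 below (−0.05), neuroendocrine markers 2 and 5 (−0.17), and immune and endothelial markers 5 and 5 (−0.02).

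The genes with the smallest p for BDB at 1e-06 M did not pass (adjusted p = 1 for each). Above DMSO were POFUT3 (0.59 ± 0.15), the metallothionein pseudogene MT1DP (1.3 ± 0.38, with 1 of 4 DMSO arrays above background), the aquaporin gene MIP (0.77 ± 0.27), EBLN3P (0.27 ± 0.1), FGF14-AS2 (0.54 ± 0.2) and the mitochondrial deacetylase SIRT3 (0.25 ± 0.1). Below DMSO were the homeobox gene HOXC5 (−0.78 ± 0.22), BABAM1 (−0.31 ± 0.1), DNAI3 (−0.91 ± 0.3), CA12, TMEM204 (−1.05 ± 0.37) and the kinase TNIK (−0.79 ± 0.28). In limma 234 probes had an unadjusted p under 0.05, 91 higher and 143 lower (151 to 512 with 1 array left out, 169 to 1943 over the other settings). When adjusted over the list alone, 0 list members passed. Within slides 1, 2 and 3, 7 of the 10 list medians kept 1 sign, and the exceptions were the matrix list (−0.37, −0.26 and 0.02), hypoxia (−0.16, −0.16 and 0.03) and immediate early genes (−0.25, 0.13 and −0.04), which lost its call with slide as a block (median −0.1, adjusted p = 0.094). Leaving out 1 array ended calls: hypoxia (median −0.03), immediate early genes (0.11) and TGF-beta targets (−0.07) without DMSO replicate 1, estrogen response (−0.12), histones (−0.08), basal (−0.08) and fibroblast markers (−0.05) without DMSO 3, TGF-beta targets (−0.14) and fibroblast markers (−0.07) without DMSO 4, hypoxia (−0.12), estrogen response (−0.1), histones (0.13) and fibroblast markers (−0.09) without BDB 1, hypoxia (−0.09) and immediate early genes (−0.13) without BDB 2, hypoxia (−0.09), immediate early genes (−0.11), TGF-beta targets (−0.11) and cholesterol (0.05) without BDB 3, and histones (0.09) without BDB 4. Other settings ended the fibroblast call (no probe filter, array weights), the estrogen call (stricter filter, array weights) and those of histones, hypoxia and immediate early genes (array weights). They added neuroendocrine markers (no filter), ribosomal proteins (quantile normalisation), metallothioneins (array weights) and interferon (array weights, without the 5 samples).

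With BDB at 1e-08 M the interferon response list fell, with 21 of 22 members below DMSO and a median of −0.29. IFI44L was −0.9 ± 0.34 and MX2, an antiviral GTPase, −0.63 ± 0.22, and IFIT2 at 0.11 ± 0.14 was the member above DMSO. All 17 immediate early genes lay above DMSO (median 0.3), with NR4A1 at 0.82 ± 0.59 and EGR1 at 0.73 ± 0.49. In limma's camera the adjusted p was 3.9e-11 for interferon and 7.4e-05 for immediate early genes. Neither call held with an estimated correlation (adjusted p = 0.54 and adjusted p = 0.85). BDB low-dose replicates 2 and 4 and DMSO replicate 1 were among the 5 samples with high immediate early scores, and without those 5 the median was 0.19 and the call stayed.

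Oxidative phosphorylation also fell with BDB at 1e-08 M, with 20 of 23 members below DMSO (median −0.11, adjusted p = 0.00047). The complex I subunits NDUFB8 and NDUFA9 were each −0.19 ± 0.11, NDUFS1 0.04 ± 0.09 and NDUFB5 0.03 ± 0.18. Ribosomal protein genes fell, 24 of 25 being below DMSO by small amounts (median −0.08, adjusted p = 0.008), with RPL4 at −0.16 ± 0.07, RPL11 at −0.16 ± 0.11 and RPS2 at 0.01 ± 0.14. Fibroblast and smooth muscle markers fell in 7 of 8 (median −0.32, adjusted p = 0.0044), with POSTN at −0.61 ± 0.71, COL1A1 at −0.48 ± 0.27 and THY1 at 0.01 ± 0.17. The 13 histone genes all lay above DMSO (median 0.13, adjusted p = 0.043), with H2BC11 at 0.31 ± 0.26 and H2AC8 at 0.23 ± 0.26. With an estimated correlation these calls were lost (adjusted p = 0.54 for fibroblast markers and adjusted p = 0.85 for the other lists). The other 26 lists did not pass, with medians from −0.11 (luminal markers) to 0.07 (hypoxia).

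For BDB at 1e-08 M the genes with the smallest p lay above DMSO for DPY19L2P2 (0.78 ± 0.23), ZNF99 (0.36 ± 0.11), LPP (0.63 ± 0.19), ZNF714 (0.27 ± 0.09) and the golgin GCC2 (0.34 ± 0.11). They lay below for CYRIA (−0.83 ± 0.21), the GTPase RHOU (−0.43 ± 0.13), the interferon-induced IFI35 (−0.42 ± 0.13), GRHPR (−0.33 ± 0.1), the class I gene HLA-F (−0.28 ± 0.09) and LGALS9C (−0.48 ± 0.15). None passed (adjusted p = 1 for each). In limma 1040 probes had an unadjusted p under 0.05, 749 higher and 291 lower (488 to 2982 with 1 array left out, 918 to 3693 over the other settings). When adjusted over the list alone, 0 list members passed. All 6 list medians kept 1 sign within the 3 slides (interferon −0.34, −0.09 and −0.35, immediate early genes 0.04, 0.35 and 0.65), and with slide as a block histones lost their call (median 0.13, adjusted p = 0.065). Calls also ended for histones (0.2) and ribosomal proteins (−0.07) without DMSO replicate 1, histones (−0.07) and fibroblast markers (−0.2) without DMSO 3, histones without BDB 2 (0.09) or BDB 4 (0.07), ribosomal proteins without BDB 3 (−0.04), and histones (0.01) and ribosomal proteins (−0.09) without the 5 samples. The call of oxidative phosphorylation ended with the authors' values. So did that of ribosomal proteins, also with quantile normalisation, and that of fibroblast markers, also with array weights. Histones lost theirs with array weights, no intensity trend and the mean over probes. Basal markers were added with no filter and without the 5 samples, where matrix, heat shock, mitosis, NF-kB and glycolysis lists also passed.

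With HDB at 1e-06 M the extracellular matrix and EMT list fell, with 22 of 24 members below DMSO and a median of −0.18. MMP9 was −0.78 ± 0.41 and COL1A1 −0.61 ± 0.27, against ZEB1 at 0.05 ± 0.1 and SPARC at 0.02 ± 0.15. Basal epithelial markers lay below DMSO in 14 of 15 (median −0.15), with KRT5 at −0.88 ± 0.57, COL17A1 at −0.56 ± 0.35 and LAMA3, a laminin chain, at 0.02 ± 0.25. Fibroblast and smooth muscle markers lay below in 7 of 8 (median −0.17), with CNN1 at −0.37 ± 0.16 and POSTN at 0.14 ± 0.71. The camera adjusted p was 4.8e-08, 2.7e-05 and 0.00026 in that order, and each call was lost with an estimated correlation (adjusted p = 0.096 for all 3).

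Androgen response genes also fell with HDB at 1e-06 M, with 13 of 16 below DMSO (median −0.08, adjusted p = 0.032). ZBTB10 was −0.86 ± 0.32, STEAP4, a metalloreductase, −0.73 ± 0.31, HERC3 0.34 ± 0.25 and TPD52 0.01 ± 0.1. Oxidative phosphorylation rose, with 17 of 23 above DMSO (median 0.04, adjusted p = 0.032), COX7B at 0.22 ± 0.12, ATP5F1C at 0.14 ± 0.09, SDHA at −0.09 ± 0.1 and ATP5F1B at −0.07 ± 0.12. Glycolysis fell in 14 of 17 (median −0.07, adjusted p = 0.033), with HK2 at −0.37 ± 0.27, the lactate transporter SLC16A3 at −0.19 ± 0.16, PFKL at 0.08 ± 0.29 and PFKM at 0.07 ± 0.09. None of these calls held with an estimated correlation (adjusted p = 0.096 for androgen response, adjusted p = 0.61 for oxidative phosphorylation and adjusted p = 0.58 for glycolysis), and all 3 ended without the 5 samples with high immediate early genes (medians −0.02, 0.03 and −0.06). The other 26 lists did not pass, with medians from −0.13 (immediate early genes) to 0.12 (histones), and histones passed with slide as a block (median 0.15, adjusted p = 0.043).

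With HDB at 1e-06 M the genes with the smallest p above DMSO were POPDC1-AS1 (1.5 ± 0.43, with 2 of 4 DMSO arrays above background), MT1DP (1.04 ± 0.38), the kinase gene BMX, ZNF138 (0.29 ± 0.11), MIP (0.7 ± 0.27) and FBXL5 (0.22 ± 0.09). BMX lay above background on 0 of 4 DMSO arrays, and its group means differed by at least 2.05-fold, a bound that holds no sampling error. Below were RHOU (−0.44 ± 0.13), HOXC5 (−0.7 ± 0.22), the keratin KRT17 (−0.38 ± 0.13), OTOP2 (−0.55 ± 0.2), HHIPL2 (−0.74 ± 0.28) and ZBTB10. None passed (adjusted p = 1 for each). In limma 204 probes had an unadjusted p under 0.05, 70 higher and 134 lower (130 to 527 with 1 array left out, 118 to 621 over the other settings). When adjusted over the list alone, 0 list members passed. Within the slides 4 of the 6 list medians kept 1 sign, and androgen response (−0.11, −0.14 and 0.05) and oxidative phosphorylation (0.28, 0.14 and −0.15) did not. Calls ended for androgen response (−0.02), glycolysis (−0.06) and oxidative phosphorylation (0.03) without DMSO replicate 1, the same lists (−0.08, −0.08 and 0.04) and fibroblast markers (−0.14) without DMSO 3, androgen response (−0.04) and oxidative phosphorylation (−0.01) without HDB 1, androgen response (−0.08) and glycolysis (−0.03) without HDB 2, androgen response (−0.07) and oxidative phosphorylation (0.03) without HDB 3, and glycolysis (−0.08) and fibroblast markers (−0.08) without HDB 4. Androgen response lost its call with normexp, the authors' values, either change of the probe filter, array weights and the mean over probes. Glycolysis lost its call with no filter, replicate number as a block, no trend and array weights, and oxidative phosphorylation with no filter. Heat shock, hypoxia and TGF-beta lists were added with normexp, quantile normalisation and the authors' values, and histones without the 5 samples.

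With HDB at 1e-08 M the interferon response list fell, with 21 of 22 members below DMSO and a median of −0.31. IFI44L was −0.85 ± 0.34, MX2 −0.61 ± 0.22, and OASL 0.01 ± 0.13. Of the immediate early genes 15 of 17 lay above DMSO (median 0.22), with EGR1 at 0.64 ± 0.49, NR4A1 at 0.6 ± 0.59, EGR2 at −0.08 ± 0.32 and MYC at −0.07 ± 0.16. Oxidative phosphorylation fell in 20 of 23 (median −0.07), with COX7B at −0.22 ± 0.12, ATP5MC1 at −0.22 ± 0.09, SDHA at 0.06 ± 0.1 and ATP5F1B at 0.04 ± 0.12. The NRF2 oxidative stress response fell in 16 of 20 (median −0.16), with OSGIN1 at −0.4 ± 0.18, SRXN1 at −0.28 ± 0.13, GCLM, a subunit of the enzyme that starts glutathione synthesis, at 0.31 ± 0.17, and HMOX1 at 0.05 ± 0.13.

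For HDB at 1e-08 M the camera adjusted p was 1.2e-11 for interferon, 0.00085 for immediate early genes, 0.0059 for oxidative phosphorylation and 0.0076 for NRF2. All 4 calls were lost with an estimated correlation (adjusted p = 0.69 for interferon and NRF2, adjusted p = 0.95 for the others). HDB low-dose replicates 3 and 4 and DMSO replicate 1 were among the 5 samples with high immediate early and low NRF2 scores, and without those 5 both calls ended (medians 0.17 and −0.1). The other 28 lists did not pass, with medians from −0.22 (fibroblast and smooth muscle markers) to 0.1 (epithelial junctions), and the former passed with slide as a block (median −0.27, adjusted p = 0.019). The smooth muscle actin gene ACTA2 (−0.38 ± 0.1) was the 1 list member that passed when adjusted over the list alone (adjusted p = 0.0095), and over all probes it did not.

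Of the genes with the smallest p for HDB at 1e-08 M, those above DMSO were the kinase HIPK2 (0.56 ± 0.17), APC (0.37 ± 0.12), the MAP kinase phosphatase DUSP6 (0.41 ± 0.13), INO80D (0.45 ± 0.15, with another probe of opposite sign), NFAT5 (0.38 ± 0.13) and MT1DP (1.12 ± 0.38). Those below were ACTA2, METTL22 (−0.27 ± 0.08), MARCHF3 (−0.49 ± 0.16), the mitochondrial carrier SLC25A4 (−0.26 ± 0.09), ITPA (−0.26 ± 0.09) and FSTL1 (−0.24 ± 0.08). None passed (adjusted p = 1 for each). In limma 477 probes had an unadjusted p under 0.05, 247 higher and 230 lower (153 to 1982 with 1 array left out, 326 to 1717 over the other settings). Within the slides interferon kept its sign (−0.24, −0.1 and −0.57), as did NRF2, while immediate early genes (−0.18, 0.75 and −0.17) and oxidative phosphorylation (−0.12, 0.01 and −0.26) did not. Calls ended for immediate early genes without DMSO replicate 3 (0.04) or HDB 4 (0.06), for NRF2 without DMSO 4 (−0.1), HDB 1 (−0.14) or HDB 3 (−0.08), and for oxidative phosphorylation without HDB 1 (−0.08) or HDB 2 (−0.07). Quantile normalisation ended the calls of oxidative phosphorylation and NRF2, and the authors' values that of oxidative phosphorylation. Histones were added by normexp, the authors' values, no filter, replicate number as a block, array weights and the fit without the 5 samples. Junctions were added by array weights and the mean over probes, ribosomal proteins by array weights, and ribosomal, fibroblast, heat shock and fatty acid synthesis lists without the 5 samples.

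**Figure D2:**
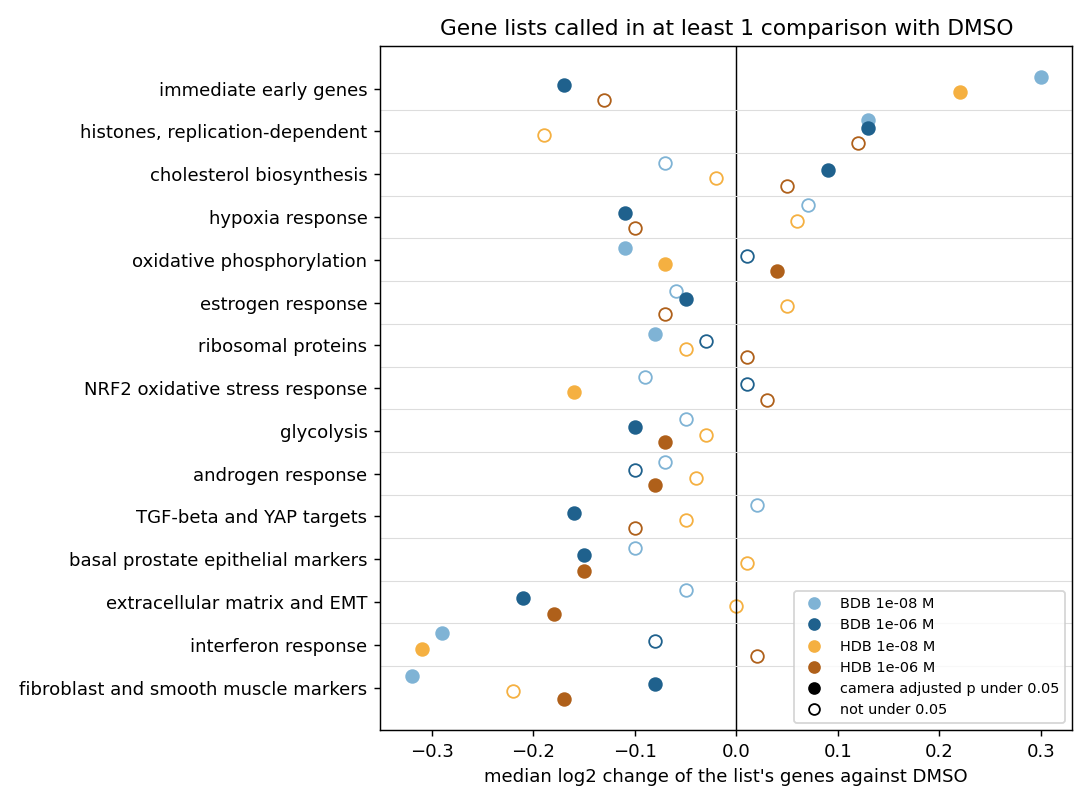
Median log2 change against DMSO (horizontal axis) of the genes on each list that camera called in at least 1 comparison with DMSO, with 1 point per list and treatment and filled points where the adjusted p was under 0.05. Interferon response lies at −0.29 and −0.31 at 1e-08 M, and the matrix list at −0.21 and −0.18 at 1e-06 M, for BDB and HDB in that order.

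The comparisons with DMSO share the same 4 control arrays, so a deviation of those arrays enters all of them. Across 28221 probes the changes for BDB and HDB at 1e-06 M correlated with r = 0.63, and those at 1e-08 M with r = 0.57. Between the doses of BDB r was 0.21, and between those of HDB 0.11. It was 0.23 for BDB at 1e-08 M with HDB at 1e-06 M, and 0.11 for BDB at 1e-06 M with HDB at 1e-08 M. Simulated data without any change but with shared controls gave 0.5 for each pair. The simulation drew every probe independently, and the pairs lay on both sides of 0.5. It therefore cannot tell whether the compounds were alike at the same dose beyond the shared controls. With the DMSO arrays split between the compounds the mean r over 6 splits was −0.16 at 1e-06 M and −0.04 at 1e-08 M. Probes are not independent replicates.

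The compounds were then compared at matched doses. At 1e-06 M BDB and HDB differed in the interferon list, 20 of 22 members being lower with BDB (median difference −0.09), with OAS1 at −0.2 ± 0.2, IFI44 at −0.18 ± 0.19, MX1 at 0.01 ± 0.23 and XAF1 at 0 ± 0.14. Cholesterol biosynthesis was higher with BDB in 17 of 24 (median 0.03), with INSIG1 at 0.14 ± 0.22, SC5D at −0.1 ± 0.19 and HSD17B7 at −0.06 ± 0.14. The camera adjusted p was 0.0063 for interferon and 0.031 for cholesterol, and both calls were lost with an estimated correlation (adjusted p = 0.91 for each). The other 30 lists did not pass, with medians from −0.05 (p53 and DNA damage response) to 0.1 (immune and endothelial markers), and ribosomal proteins passed with slide as a block (median −0.05, adjusted p = 0.017).

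Single genes did not pass between the compounds at 1e-06 M (adjusted p = 1 for each). Higher with BDB were HAR1B (0.6 ± 0.2), KCTD16 (1.08 ± 0.39), CADPS2 (0.8 ± 0.3), CAMSAP3 (0.53 ± 0.2), BRSK1 (0.55 ± 0.22) and KRTAP5-10 (1.37 ± 0.55). Higher with HDB were LRCOL1 (−0.51 ± 0.19 for BDB against HDB), PRUNE1 (−0.41 ± 0.16), PSG8-AS1, DBF4B (−0.46 ± 0.2), PRPSAP2 (−0.16 ± 0.07) and POPDC1-AS1 (−0.98 ± 0.43). PSG8-AS1 lay above background on 0 of 4 BDB and 2 of 4 HDB arrays, and its group means differed by at least 1.62-fold, again without sampling error. In limma 81 probes had an unadjusted p under 0.05, 49 higher and 32 lower with BDB (62 to 392 with 1 array left out, 26 to 1475 over the other settings). When adjusted over the list alone, 0 list members passed. The 95% interval of the difference, not adjusted for the number of probes, lay within 1.5-fold for 67% of probes and within 2-fold for 92.8%. Larger differences were thus not excluded for the other probes, nor for all of these probes at once. The sign of neither list median held within all slides (interferon −0.21, −0.33 and 0.2, cholesterol −0.23, 0.22 and 0.04), and cholesterol lost its call with slide as a block (median 0.02, adjusted p = 0.26). The interferon call ended without BDB replicate 1 (0.01), HDB 2 (−0.01) or HDB 3 (−0.01), and the cholesterol call without BDB 2 (0.02), BDB 3 (0.03), HDB 2 (0.03), HDB 3 (0.02) or HDB 4 (0.01). With no probe filter or no intensity trend cholesterol also lost its call.

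At 1e-08 M the compounds differed in the histone list, all 13 genes being higher with BDB, by a median of 0.34, with H2AC6 at 0.59 ± 0.28 and H2BC11 at 0.56 ± 0.26. Basal markers were lower with BDB in 12 of 15 (median −0.09), with KRT5 at −0.86 ± 0.57, COL17A1 at −0.52 ± 0.35, LAMA3 at 0.1 ± 0.25 and LAMB3 at 0.09 ± 0.12. The unfolded protein response was higher with BDB in 16 of 20 (median 0.04), with CHAC1 at 0.69 ± 0.39 and asparagine synthetase, ASNS, at 0.59 ± 0.27, which are targets of ATF4, while the chaperones PDIA6 and HSP90B1 were −0.15 ± 0.14 and −0.09 ± 0.11. Immune and endothelial markers were lower with BDB in 8 of 10 (median −0.15), with CSF1R at −0.41 ± 0.24, PTPRC at −0.3 ± 0.36, CD3D at 0.04 ± 0.31 and VWF at 0.02 ± 0.18. The camera adjusted p was 5.5e-07 for histones, 0.011 for basal markers and 0.049 for the unfolded protein response and for immune and endothelial markers. With an estimated correlation all 4 calls were lost (adjusted p = 0.48 for basal markers and adjusted p = 0.68 for the others). The other 28 lists did not pass, with medians from −0.19 (xenobiotic response) to 0.22 (neuroendocrine markers).

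Between the compounds at 1e-08 M the genes with the smallest p were higher with BDB for TUBE1 (0.31 ± 0.1), ZNF354C (0.49 ± 0.17), ZNF41 (0.8 ± 0.27), SUGT1P3 (0.88 ± 0.3), TSNAX (0.38 ± 0.14) and the acyl-CoA thioesterase ACOT12 (1.4 ± 0.52). They were lower with BDB for CA12 (−0.69 ± 0.21), SHF (−0.4 ± 0.12), ZNF683 (−0.79 ± 0.24), KRTDAP (−1.03 ± 0.35), ADGRF1 (−1.43 ± 0.49) and SPMIP8 (−0.76 ± 0.26). None passed (adjusted p = 1 for each). In limma 372 probes had an unadjusted p under 0.05, 231 higher and 141 lower (138 to 1328 with 1 array left out, 309 to 1295 over the other settings). When adjusted over the list alone, 0 list members passed. The interval lay within 1.5-fold for 63.1% of probes and within 2-fold for 91.3%. Within the slides the histone medians were 0.59, −0.15 and 1.03 and those of the unfolded protein response 0.05, −0.03 and 0.22, and with slide as a block the latter (median 0.07) and the immune and endothelial list (−0.12) lost their calls (adjusted p = 0.066 for each). The unfolded protein response call ended without BDB replicate 2 (0.06), BDB 4 (0.06), HDB 1 (0.06) or the 5 samples with high immediate early genes (0.09), the immune and endothelial call without BDB 2 (−0.08), BDB 4 (−0.08), HDB 3 (−0.09), HDB 4 (−0.1) or the 5 samples (0.08), and the basal call without BDB 3 (−0.09) or HDB 1 (−0.08). With no filter, no trend or the mean over probes the unfolded protein response and the immune and endothelial list lost their calls, the latter also with array weights. TGF-beta and YAP targets were added with normexp, quantile normalisation, replicate number as a block and array weights, xenobiotic response and immediate early genes with array weights, and mitosis without the 5 samples.

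The doses of each compound were compared last. For BDB the genes with the smallest p were higher at 1e-06 M than at 1e-08 M for LRRC40 (0.31 ± 0.09), THTPA (0.35 ± 0.1) and USP18, an interferon-induced protease (0.43 ± 0.13), and lower for the cadherin FAT1 (−0.7 ± 0.19), the long non-coding RNA KCNQ1OT1 (−1.53 ± 0.42) and the histone methyltransferase KMT2A (−0.7 ± 0.2). For HDB they were higher for EMC9 (0.5 ± 0.12), ECI1, an enzyme of fatty acid oxidation (0.42 ± 0.1), and BBIP1 (0.62 ± 0.16), and lower for GAL3ST1 (−0.91 ± 0.23), the granin SCG2 (−1.39 ± 0.36) and CREB3L2 (−0.57 ± 0.15). None passed in limma (lowest adjusted p = 0.846 for BDB and 0.564 for HDB). At an unadjusted p under 0.05 there were 1589 probes for BDB, 498 higher and 1091 lower, and 2395 for HDB, 1392 higher and 1003 lower. With 1 array left out these counts ran from 588 to 2538 for BDB and from 1351 to 3676 for HDB, and over the other settings from 574 (without the 5 samples) to 5150 (array weights) for BDB and from 1689 (without the 5 samples) to 2826 (no probe filter) for HDB.

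The lists were tested between the doses after the data were seen, and camera called 8 lists for BDB. Higher at 1e-06 M than at 1e-08 M were interferon response in 18 of 22 members (median 0.21, adjusted p = 3.3e-05), oxidative phosphorylation in 22 of 23 (0.12, adjusted p = 0.00011), cholesterol biosynthesis in 22 of 24 (0.14, adjusted p = 0.00015) and ribosomal proteins in 22 of 25 (0.06, adjusted p = 0.045). Lower were all 17 immediate early genes (−0.39, adjusted p = 1.8e-07), TGF-beta and YAP targets in 15 of 16 (−0.2, adjusted p = 0.0058), the matrix list in 21 of 24 (−0.17, adjusted p = 0.0067) and the hypoxia response in 17 of 20 (−0.18, adjusted p = 0.01). With an estimated correlation all 8 calls were lost (adjusted p = 0.8 for ribosomal proteins and adjusted p = 0.43 to 0.45 for the others). BDB low-dose replicates 2 and 4 were among the 5 samples with high immediate early genes. Without those 5, hypoxia (−0.06), TGF-beta targets (−0.03) and the matrix list (−0.04) lost their calls, and immediate early genes (−0.14) kept theirs. The other 24 lists did not pass, with medians from −0.13 (epithelial junctions) to 0.13 (xenobiotic response), and 0 list members passed when adjusted over the list alone.

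Within slides 1, 2 and 3 the medians of interferon between the BDB doses were −0.02, 0.27 and 0.49, those of ribosomal proteins −0.04, 0.13 and 0.16, those of the matrix list −0.29, 0.01 and −0.09, and those of cholesterol 0, 0.26 and 0.07. The other 4 lists kept 1 sign. Ribosomal proteins lost their call with slide as a block (median 0.06, adjusted p = 0.11), and also without BDB mid-dose replicate 2 (0.05) or 4 (0.04) or low-dose replicate 1 (0.09) or 3 (0.04). Hypoxia lost it without mid-dose replicate 1 (−0.17) or low-dose replicate 4 (−0.09), and the matrix list without mid-dose replicate 1 (−0.14) or low-dose replicate 2 (−0.1). The ribosomal call also ended with quantile normalisation, the authors' values, either change of the filter and replicate number as a block. Junctions were added with normexp, the authors' values and the mean over probes, NRF2 with the mean over probes, and glycolysis with quantile normalisation and the authors' values. Without the 5 samples histones, heat shock, p53, NF-kB and metallothionein lists were added.

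For HDB camera called 9 lists between the doses. Higher at 1e-06 M were interferon response in 21 of 22 members (median 0.31, adjusted p = 7.2e-07), oxidative phosphorylation in 19 of 23 (0.1, adjusted p = 0.00069), NRF2 response in 16 of 20 (0.19, adjusted p = 0.004) and all 13 histone genes (0.29, adjusted p = 0.0066). Lower were immediate early genes in 16 of 17 (−0.4, adjusted p = 0.00052), the matrix list in 19 of 24 (−0.19, adjusted p = 0.00077), basal markers in 13 of 15 (−0.19, adjusted p = 0.004), epithelial junctions in 14 of 21 (−0.17, adjusted p = 0.013) and the hypoxia response in 12 of 20 (−0.08, adjusted p = 0.042). None of the 9 calls held with an estimated correlation (adjusted p = 0.71 for histones and adjusted p = 0.4 to 0.45 for the others). HDB low-dose replicates 3 and 4 were among the 5 samples, and without those 5 the calls ended for NRF2 (0.12), hypoxia (0.04), the matrix list (−0.16) and immediate early genes (0), while histones moved to 0.6. The other 23 lists did not pass, with medians from −0.17 (estrogen response) to 0.13 (p53 and DNA damage response). When adjusted over the list alone 16 members passed, 8 of interferon response, 3 of oxidative phosphorylation, 2 of neuroendocrine markers, and 1 each of immediate early genes, PPAR targets and the unfolded protein response.

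Between the HDB doses 7 of the 9 list medians kept 1 sign within the slides, among them interferon (0.13, 0.55 and 0.4), and basal markers (0.02, −0.24 and −0.26) and immediate early genes (−0.22, −0.62 and 0.12) did not. With slide as a block hypoxia lost its call (median −0.09, adjusted p = 0.051) and ribosomal proteins gained one (0.09, adjusted p = 0.042). Calls ended for histones without HDB mid-dose replicate 1 (0.19) or 2 (0.21) or low-dose replicate 1 (0.12) or 2 (0.21), for hypoxia without mid-dose replicate 1 (−0.08) or 4 (−0.05) or low-dose replicate 3 (−0.04) or 4 (−0.1), and for basal markers without low-dose replicate 1 (−0.17). Hypoxia also lost its call with replicate number as a block, no trend, array weights and the mean over probes. Heat shock was added with normexp, quantile normalisation and the authors' values, glycolysis with quantile normalisation and the authors' values, and ribosomal proteins with array weights. Without the 5 samples ribosomal, fatty acid synthesis and unfolded protein lists were added.

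**Figure D3:**
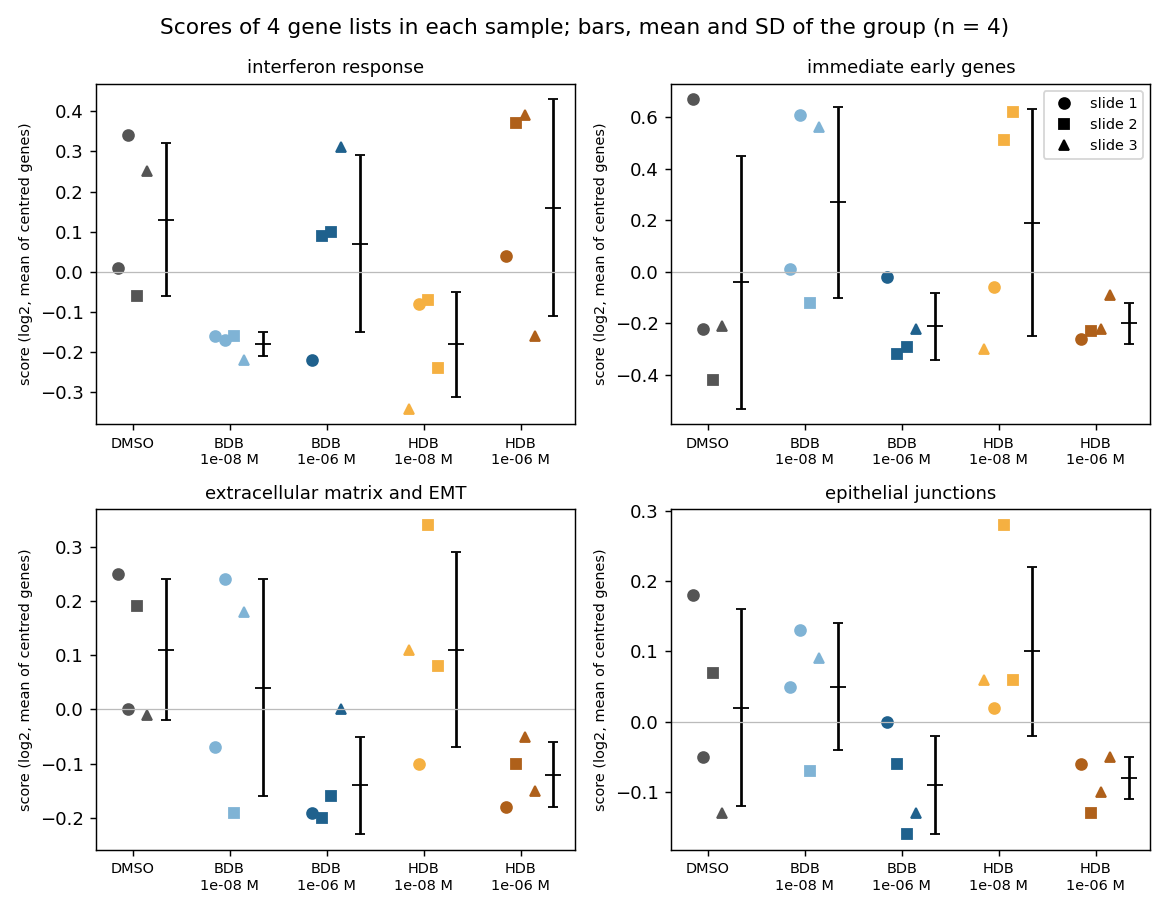
Scores of interferon response, immediate early genes, extracellular matrix and EMT, and epithelial junctions in each sample (vertical axes, log2, mean of centred genes) by group, with the shape giving the slide and the bar the mean and SD of 4 samples. Interferon scores average −0.18 in both groups at 1e-08 M, 0.13 in DMSO, 0.07 with BDB and 0.16 with HDB at 1e-06 M.

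Genes fixed in advance as markers of xenobiotic, lipid and stress responses gave 0 calls. Over the 4 comparisons with DMSO, PLIN2, which coats lipid droplets, changed by −0.11 to 0.09 (outer 95% bounds −0.36 and 0.34), PDK4 by −0.04 to 0.03 (−0.66 and 0.66), HMGCS1, an enzyme of sterol synthesis, by −0.12 to 0.08, and ANGPTL4 by −0.29 to −0.03 (−0.79 and 0.46). CYP1A1, the classic target of the aryl hydrocarbon receptor, changed by 0.16 to 0.31 (−0.33 and 0.79), and CYP1B1 by −0.34 to 0.24 (−0.92 and 0.82). The CYP1B1 level was 1.52 to 1.88 in the 5 samples with high immediate early genes and 2.45 to 2.83 in the others. The NRF2 targets HMOX1 and NQO1 changed by −0.13 to 0.05 and −0.05 to 0.01. DDIT3, a factor of the unfolded protein response, changed by −0.43 to 0.38 (−0.91 and 0.86), CDKN1A, the p53 target, by −0.53 to 0.07 (−1.16 and 0.69), and MKI67, a proliferation marker, by −0.11 to 0.43 (−0.57 and 0.89). KRT5 changed by −1.04 to −0.18 (−2.24 and 1.02), and the luminal keratin KRT18 by −0.1 to −0.02. None passed in limma (adjusted p = 1 for each).

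**Figure D4:**
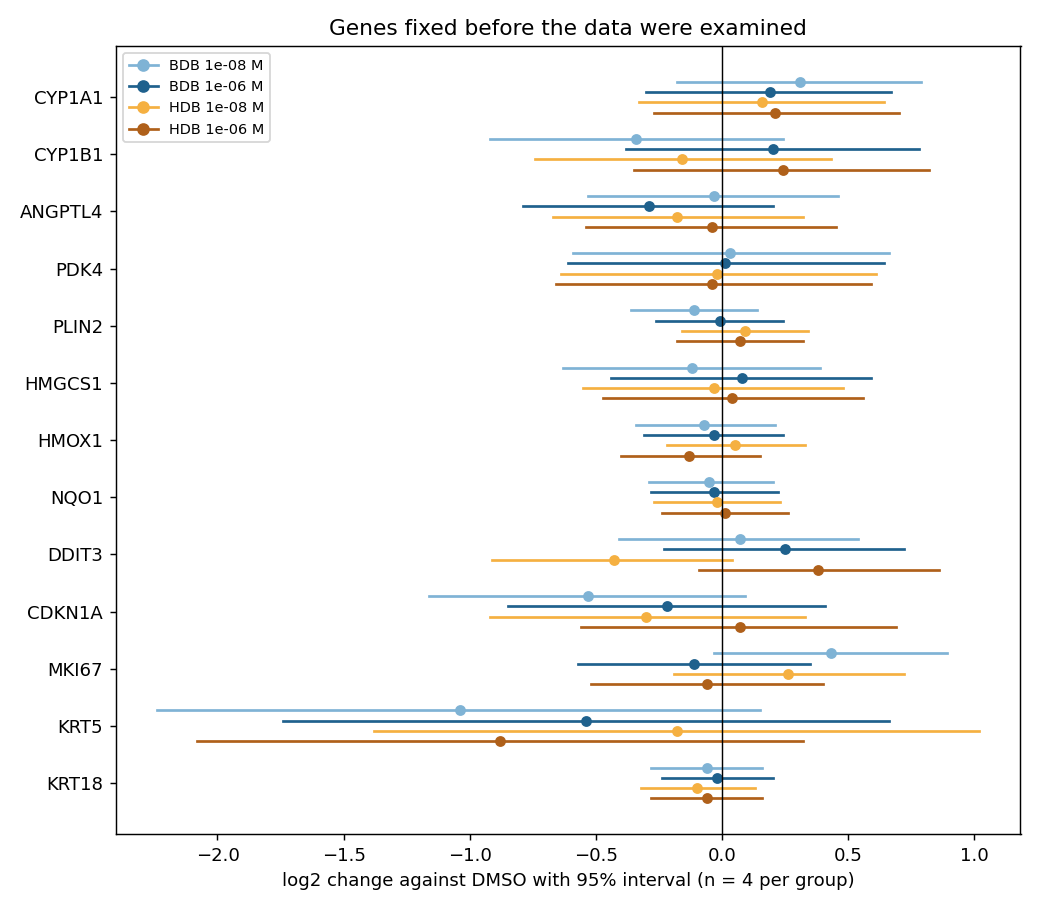
Log2 change against DMSO (horizontal axis) of genes fixed in advance, with 1 point per gene and treatment and its 95% interval as a line (4 samples per group). Every interval drawn includes 0, and KRT5 has outer bounds of −2.24 and 1.02.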

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

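The counts of splits were planned except those of lists between doses, which were added after seeing the data, and the tests on the 5 samples with high immediate early genes were chosen after those samples were seen. A sample was picked out when its gap to the nearest of the other 3 in its group filled more than 0.829 of the group's range (Dixon's limit), which chance gives in about 1 in 20 groups. Of 180 groups of list scores and array measures 8 held such a sample, of 65 groups of the fixed genes 2, and of 795 groups of the other named genes 42.

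DMSO replicate 1 stood apart in heat shock genes (score 0.14 against −0.02 to 0 in the other DMSO samples), p53 and DNA damage genes (−0.17 against 0.09 to 0.11), hypoxia genes (0.24 against −0.09 to −0.04) and the log2 level of CYP1B1 (1.58 against 2.61 to 2.73). HDB mid-dose replicate 1 stood apart in cholesterol biosynthesis (0.17 against −0.03 to −0.01) and luminal markers (0.13 against −0.14 to −0.11). BDB low-dose replicate 3 did so in the unfolded protein response (−0.05 against 0.08 to 0.1) and neuroendocrine markers (0.01 against 0.11 to 0.13), and HDB low-dose replicate 3 in epithelial junctions (0.28 against 0.02 to 0.06). PDK4 in BDB mid-dose replicate 1 was −3.44 against −4.08 to −4.05.

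Between the compounds camera called lists at each dose, as a test of the difference itself. At 1e-06 M the median difference of BDB against HDB was 0.03 for cholesterol biosynthesis and −0.09 for interferon response. At 1e-08 M it was 0.34 for histones, 0.04 for the unfolded protein response, −0.09 for basal markers and −0.15 for immune and endothelial markers. All 6 calls were lost with an estimated correlation (lowest adjusted p 0.91 at 1e-06 M and 0.48 at 1e-08 M) and with fry (0.97 and 0.87).

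The 5 samples with high immediate early genes also differed from the other 15 in genes of other lists. The YAP target ANKRD1 was −1.28 to −0.89 in them against −4.21 to −2.42, and the hypoxia target BNIP3 3.01 to 3.16 against 1.84 to 2.3. The p53 targets DDB2 (0.66 to 0.9 against 1.6 to 2.04) and TP53I3 (0.82 to 1.07 against 1.58 to 2.34) were lower, as was ALDH3A1 (−1.35 to −0.91 against 0.41 to 0.95). These genes were chosen after their values were seen. The slides argue against a slide effect, since 4.95% of the variance of the immediate early score lay between slides. For array brightness, the 75th percentile of 4 of the 5 lay within the range of the other 15 (575.2 to 813.6 against 629.8 to 891.3). HDB low-dose replicate 4, at 575.2, was the dimmest of the 20 arrays. Most of any 5 arrays may fall within the range of 15 others, so this cannot exclude a part played by brightness. Dose stays open: 4 of the 8 samples at 1e-08 M, 0 of the 8 at 1e-06 M and 1 DMSO sample were high, with an exact two-sided permutation p of 0.009 between the doses, so dose alone would leave the DMSO sample and the 4 low-dose samples with lower scores unaccounted for. Handling of the cells at harvest may be another candidate explanation, and the labels record nothing that would test it.

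Other splits of the same samples tell how far chance can account for the counts. For the lists, 35 splits of the 8 samples of each comparison were counted, the real one included. As many lists or more came from 4 splits for BDB at 1e-06 M (10 real, 12 highest other), 14 for BDB at 1e-08 M (6 and 10), 11 for HDB at 1e-06 M (6 and 10) and 29 for HDB at 1e-08 M (4 and 11). Between the compounds 29 splits did so at 1e-06 M (2 and 8) and 27 at 1e-08 M (4 and 13). Between the doses 9 splits did so for BDB (8 and 16) and 4 for HDB (9 and 11). Chance can therefore not be excluded for any of the 8 list counts.

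For probes the real count was 0 in all 8 comparisons, so 35 of 35 splits reached it in each, and 100 of 100 splits of the 20 samples reached the 0 of the F-test (highest other 699). The highest other split called 0 probes for BDB at 1e-06 M, HDB at 1e-06 M, HDB at 1e-08 M, the compounds at 1e-06 M and the doses of BDB. It called 8 for BDB at 1e-08 M against DMSO, 4345 for the compounds at 1e-08 M and 4117 for the doses of HDB, and in each of these 3 comparisons it was the 1 split that called any. The split with 4345 set BDB low-dose replicates 2 and 4 and HDB low-dose replicates 3 and 4, the low-dose samples with high immediate early genes, against the other 4. The splits with 4117 and 8 also placed all their samples of that kind, 2 and 3, on 1 side. The split with 4117 follows the slides as well, with slides 1, 2, 2 and 2 on the side of HDB mid-dose replicates 1 and 2 and low-dose replicates 3 and 4, and slides 3, 3, 3 and 1 on the other. The real grouping by HDB dose gave 0 probes with and without slide as a block, which tells nothing about that split. The split with 4117 was not refitted with the block, so slides and the samples with high immediate early genes are not told apart for it. Such counts point to a structure of the samples that does not follow the groups.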

How the results depend on the processing

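Normexp on the median signal, the fits without the 5 arrays with high immediate early genes and the list tests between doses were chosen after seeing the data, and the planned normexp on the mean spot signal was not run because the files hold no such column. The count of probes was 0 in all 8 comparisons and in the F-test under every alternative run on the 3 slides together, and 0 to 0 with each array left out in turn. Fits within 1 slide, with 2, 2 and 1 residual degrees of freedom, called 0 to 604 probes, with 604 for the doses of HDB and 470 for HDB at 1e-08 M on slide 2, and 524 for the compounds at 1e-08 M on slide 3. Of 4611 values of named genes under alternatives, 4379 kept their direction, 232 changed sign and 0 passed the threshold (lowest adjusted p 0.08). Of 1029 list medians 774 kept their call, 247 lost it and 8 reversed. Over 11 settings, apart from the estimated correlation and fry, and 8 fits with an array left out, calls were kept throughout by the matrix list at 1e-06 M (BDB −0.22 to −0.16, HDB −0.19 to −0.13 over the settings), basal markers with HDB at 1e-06 M (−0.17 to −0.11), interferon at 1e-08 M (BDB −0.37 to −0.24, HDB −0.39 to −0.3), immediate early genes with BDB at 1e-08 M (0.18 to 0.41), and histones between the compounds at 1e-08 M (0.33 to 0.57). Between doses of BDB cholesterol (0.1 to 0.17), interferon (0.18 to 0.26), oxidative phosphorylation (0.08 to 0.17) and immediate early genes (−0.45 to −0.14) kept theirs, and between doses of HDB interferon (0.29 to 0.42), oxidative phosphorylation (0.06 to 0.2) and junctions (−0.19 to −0.1).

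With an estimated correlation between genes, and with fry, 0 lists were called in each of the 8 comparisons. The lowest adjusted p with an estimated correlation was 0.11, 0.54, 0.096 and 0.69 for BDB at 1e-06 M and 1e-08 M and HDB at 1e-06 M and 1e-08 M against DMSO, 0.91 and 0.48 between the compounds at 1e-06 M and 1e-08 M, and 0.43 and 0.4 between the doses of BDB and HDB. With fry it was 0.19, 0.6, 0.28, 0.87, 0.97, 0.87, 0.38 and 0.13. The correlations estimated within lists had a median of 0.14, above the preset 0.01, and higher correlations widen the test. Counts of called lists also moved by over 1.5 times as follows. For HDB at 1e-08 M, 2 were called with quantile normalisation, 7 with array weights and 7 without the 5 arrays, against 4. For BDB at 1e-08 M, 3 were called from the authors' values and 10 without the 5 arrays, against 6. HDB at 1e-06 M gave 3 with no probe filter, against 6. Between the compounds at 1e-06 M, 1 was called with no probe filter and 1 without the intensity trend, against 2, and at 1e-08 M 2 each with no probe filter, slide as a block, no trend and the mean over probes, against 4. The cause of these moves was not tested.

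With replicate number as a block the counts were 10, 6, 5 and 5 against DMSO in the order above, with glycolysis lost for HDB at 1e-06 M and histones gained for HDB at 1e-08 M, 2 and 5 between the compounds, and 7 and 8 between the doses, with ribosomal proteins lost for BDB and hypoxia for HDB, and 0 probes throughout. Whether the numbers pair the samples is not settled. Those of the same number correlated with a mean r of 0.063, against −0.021 for other numbers. Of the samples 10 of 20 lay closest to their own number, while 19 of 20 lay closest to their own slide. Numbers partly follow the slides, so a pairing by number is not told apart from the slides. With slide as a block the counts were 10, 5, 7, 5, 2, 2, 7 and 9, and without the 5 arrays 7, 10, 4, 7, 2, 3, 10 and 8.

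With 1 array left out the counts ran from 6 to 11 for BDB at 1e-06 M (6 without BDB replicate 3), 4 to 7 for BDB at 1e-08 M, 4 to 13 for HDB at 1e-06 M (13 without DMSO 2 and 10 without DMSO 4), and 2 to 7 for HDB at 1e-08 M (2 without HDB 1 and 7 without HDB 4). Between the compounds they ran from 0 to 3 at 1e-06 M (0 without HDB 2 or HDB 3) and 3 to 10 at 1e-08 M (7 without BDB 1 and 10 without HDB 2), and between the doses from 6 to 8 for BDB and 8 to 10 for HDB. Medians that reversed were immediate early genes with BDB at 1e-06 M (0.11 without DMSO 1, with a range of −0.33 to 0.11 over the arrays left out, and 0.11 without the 5 arrays), histones without DMSO 3 (−0.08 with BDB at 1e-06 M, range −0.08 to 0.22, and −0.07 at 1e-08 M, range −0.07 to 0.24), oxidative phosphorylation with HDB at 1e-06 M without HDB 1 (−0.01, range −0.01 to 0.11), interferon between the compounds at 1e-06 M without BDB 1 (0.01, range −0.19 to 0.01), immune and endothelial markers between them at 1e-08 M without the 5 arrays (0.08), and hypoxia between the doses of HDB without the 5 arrays (0.04, range −0.14 to −0.04 over the arrays left out). The cause was not tested beyond the arrays named.

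Signal over background limits the dim genes: 36 of the 245 gene and comparison pairs under the naming rule had a group that was not above background on all its arrays, and 2 had a group above it on none.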

Other observations

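All tests in this part were chosen after the result was seen, and they compare the 8 samples at 1e-08 M with the 8 at 1e-06 M over both compounds. That grouping by dose was not planned, and elsewhere it served only for the immediate early score. The tests of list scores are two-sided exact permutation tests over 12870 splits, adjusted over the 32 lists. Epithelial junction genes were higher at the low dose by 0.16 (mean score 0.08 ± 0.1 at 1e-08 M and −0.09 ± 0.05 at 1e-06 M, SD, n = 8), with 8 of 8 low-dose samples above the mean of the mid dose (exact p = 0.00078, adjusted p = 0.025). The scores overlapped, with BDB low-dose replicate 3 at −0.07 and BDB mid-dose replicate 1 at 0. Of the 21 junction genes 14 were lower at 1e-06 M and 7 higher. The gap junction gene GJA1 was −0.83 ± 0.28 (1e-06 M against 1e-08 M), the claudins CLDN4 and CLDN3 −0.45 ± 0.14 and −0.46 ± 0.19, plakophilin PKP1 −0.48 ± 0.19, desmoplakin DSP −0.24 ± 0.09 and TJP1 −0.16 ± 0.06, while CLDN1 was 0.22 ± 0.13. In limma 5 junction genes passed when adjusted over the list alone and 0 probes over all genes, where 4473 had an unadjusted p under 0.05.

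Interferon genes were lower at the low dose, with a score difference of −0.29 (−0.18 ± 0.09 against 0.11 ± 0.23, SD, n = 8) and 8 of 8 low-dose samples below the mean of the mid dose (exact p = 0.0048, adjusted p = 0.064). Single samples overlapped: BDB mid-dose replicate 1 (−0.22) and HDB mid-dose replicate 4 (−0.16) lay within the low-dose range of −0.34 to −0.07. IFI44L was 0.99 ± 0.24 higher at 1e-06 M, MX1 0.61 ± 0.16, MX2 0.61 ± 0.15, OAS1 0.57 ± 0.14, IRF9 0.44 ± 0.14 and IRF7 0.38 ± 0.1, and 12 of the 22 members passed in limma when adjusted over the list alone. Oxidative phosphorylation was lower at the low dose, with a difference of −0.12 (exact p = 0.019, adjusted p = 0.087). Here too 8 of 8 low-dose samples lay below the mean of the mid dose. HDB mid-dose replicate 4, however, scored −0.14, near the lowest low-dose score of −0.15. Without the 5 samples with high immediate early genes the difference was −0.18 (exact p = 0.016). COX7B was 0.41 ± 0.09 and NDUFB8 0.27 ± 0.07 for 1e-06 M against 1e-08 M. The matrix list differed by 0.2 (exact p = 0.012, adjusted p = 0.064), with THBS1 at −0.57 ± 0.14, TGFBI at −0.51 ± 0.16, SNAI1 at −0.43 ± 0.12 and SPARC at 0.35 ± 0.11, and by 0.07 without the 5 samples with high immediate early genes. Estrogen response differed by 0.12 (exact p = 0.0099, adjusted p = 0.064), and by 0.13 without the 5 samples (exact p = 0.0061). Of its 15 members, however, 9 were lower at 1e-06 M and 6 higher, with a median of −0.06. Its largest change was PDZK1 at −1.1 ± 0.3, a dim gene above background on 2 of 4 arrays with BDB at 1e-06 M. NRF2 response differed by −0.14 (exact p = 0.012, adjusted p = 0.064), with PGD at 0.41 ± 0.1, and by −0.05 without the 5 samples (exact p = 0.25). These members were chosen after their values were seen, and of these lists junctions alone passed the adjustment of the permutation test. Camera on the same grouping called 9 lists at its preset correlation and 0 with an estimated one. With the estimated correlation the adjusted p was 0.38 for junctions and for interferon.

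For the interferon difference, an offset shared by all arrays of a slide is argued against as its whole cause, since with slide as a block it was −0.29. All groups were on each slide, so the block had little room to change it. Within slides 1, 2 and 3 the difference was −0.04, −0.34 and −0.46, so slide 1 hardly showed it. A difference that depends on the slide is therefore not excluded. The 5 samples with high immediate early genes are argued against too, since without them the difference was −0.3 (exact p = 0.044). A candidate explanation is the dose of both compounds (exact p = 0.0048 before adjustment), as a hypothesis found and tested on the same data, and the score in DMSO (0.13 ± 0.19, SD, n = 4) lay near that of the higher dose. Whether the cells at each dose were cultured or harvested together is not recorded and stays open.

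For epithelial junctions the difference was 0.15 with slide as a block and 0.1, 0.2 and 0.16 within slides 1, 2 and 3, which argues against a slide effect. Without the 5 samples it was 0.1 (exact p = 0.016), which argues against those samples as its whole cause. Dose of both compounds may account for it (exact p = 0.00078), as a hypothesis from the same data, with DMSO between the doses (0.02 ± 0.14, SD, n = 4) and the same open point on culture and harvest.

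Across 28221 probes the change from 1e-08 M to 1e-06 M correlated between BDB and HDB with r = 0.5. Exchanging doses within compounds gave an r at least as high in a share of 0.0118 of 4900 splits (median 0, highest 0.65). With slide as a block r was 0.6, within slides 1, 2 and 3 it was 0.14, 0.01 and 0.07, and without the 5 samples it was 0.32 (share 0.089 of 225 splits). After the immediate early score was regressed out of each probe r was −0.05. That score itself differs between the doses, so this also removes part of any dose difference. Probes are not independent replicates.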
